A study of Mus musculus with 2 samples.

How the data were processed

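Single-cell RNA sequencing of whole lungs was analysed from 2 droplet libraries, 1 per group, each a pool of cells from 4 mice that had been labelled with hashing antibodies 1 to 4, per the labels' protocols. The mice were kept on their diets for 5 weeks. Lungs were perfused, digested with enzymes in a mechanical dissociator, and freed of red cells by lysis, and libraries were made with a 3' kit that counts molecules by UMIs. The deposited values are raw counts per gene and barcode, with counts of 4 antibody tags, made with Cell Ranger 7.0.1 per the submitters' processing notes. The genome build, the annotation and any removal of background RNA were not given in the sources used here, so no coordinates are reported. Barcodes with 0 UMIs, 135 in the control and 356 in the HFpEF library, were among those deposited.

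Barcodes were assigned to mice with HTODemux of Seurat 5.3.0 at a positive quantile of 0.99, run per library, which called 64.9% of control and 73.7% of HFpEF barcodes single cells. Barcodes called doublets or negative were left out. Kept cells had at least 500 UMIs and 200 genes and at most 10% mitochondrial UMIs. Of the barcodes past these filters, 9457 control and 9378 HFpEF barcodes were single cells, 1176 and 719 were tag doublets, and 4214 and 1907 were negative. Scrublet marked 4.60% of control and 2.38% of HFpEF single cells, which were left out, and 24.8% and 24.3% of the tag doublets. Tag numbers only name mice and pair none of them.

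Cells of both libraries were normalised to 10000 UMIs per cell in scanpy 1.11.5. They were clustered by the Leiden method (igraph 0.11.9) at resolution 1, without batch integration. Clustering used 15 neighbours and 30 principal components of 2000 variable genes. Of 32 clusters, 28 were named from marker lists fixed before the data were examined, 3 held markers of several classes and 1 could not be named. The naming rule fixed before the data were examined had no step that set mixed clusters apart. That step and its limits were set after seeing the data. Because general capillary and arterial clusters were not separated, they form 1 class.

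UMI counts were summed per mouse and class over mice with at least 20 cells. Classes of a list fixed before the data were examined, with at least 3 such mice per group, were tested with the quasi-likelihood test of edgeR 4.0.16 (TMM scaling, filterByExpr, Benjamini-Hochberg adjustment over the genes of a class, threshold 0.05). NK cell-like and venous endothelium-like cells were not on that list, so that their genes were not tested although enough mice had them. The SE of a log2 fold change was its absolute value divided by the square root of the quasi-likelihood F statistic. Gene lists with at least 4 measured members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry, adjusted over all 325 pairs of list and class. Shares of cells, Il1b as log2(CPM + 1), and differences between classes were tested with two-sided exact permutation tests over mice. Count-based values depend on the cells kept per mouse, which ranged from 1754 to 2879.

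Genes were named by a rule fixed before the data were examined. It takes genes of the interleukin 1 family in myeloid and endothelial classes. It also takes, among changed genes with at least 20 CPM and no overlap between groups, the 8 highest and the 8 lowest fold changes of a class. From each list that passed its test it takes up to 4 changed members. Among those 8 highest and lowest, symbols of predicted, mitochondrial, ribosomal and haemoglobin genes and of immunoglobulin and T cell receptor segments are left out, while a list that passed may still name ribosomal genes.

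The edgeR test was run on simulated counts with 200 changed genes. In alveolar macrophage-like cells 86% of 2-fold and 97% of 4-fold changes were recovered, and 0.12% of the genes with no change were called. In neutrophil-like cells 51% and 83% were recovered, and in the whole lung 62% and 90%. camera was run on simulated alveolar macrophage-like counts with a raised list, which it called. As genes were simulated independently, this cannot judge the preset correlation. The permutation tests of Il1b and of differences between classes were not checked on simulated counts. In simulated shares with some classes doubled, 6.13% of the other classes had an unadjusted p under 0.05. The only p under 0.05 that the splits allow is 0.0286. Doubling a class lowers the shares of all others, so that these were not strictly unchanged and the rate is not one of false calls.

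Alternatives fixed before the data were examined were other mitochondrial and UMI limits, Scrublet doublets kept, assignment by the ratio of tag counts, cluster resolutions 0.5 and 2, RLE scaling, DESeq2 1.42.0, no expression filter, cells thinned to 1000 UMIs, a minimum of 50 cells, the tag number as a block, shares within a compartment, and leaving out each mouse. Chosen after seeing the data were joining mixed clusters to classes, leaving out cells with endothelial RNA, a minimum of 10 cells and fry in either direction. Joining mixed clusters undoes their setting apart, which was itself chosen after seeing the data.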

Results

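The lungs of mice on a low-fat diet with regular water (control) were compared with those of mice given a high-fat diet and L-NAME, an inhibitor of nitric oxide synthases, in the drinking water for 5 weeks. The combination is a mouse model of heart failure with preserved ejection fraction (HFpEF), in which the left ventricle empties normally but fills poorly. Each group had 4 mice of the strain C57/BL6. Whole lungs were digested, the cells of each mouse were labelled with a hashing antibody that carries a sequence tag, and the 4 mice of a group were pooled into 1 droplet library, so that mice are the replicates. Group and library were the same split, and a difference between libraries cannot be told apart from a difference between groups. The control library held 103965721 unique molecular identifier (UMI) counts in 19995 barcodes and the HFpEF library 94012480 in 15171 barcodes. After filters, 9022 control cells with a median of 4469 UMIs and 9155 HFpEF cells with a median of 4574 UMIs were assigned to a mouse. Kept UMIs per mouse ranged from 13311667 to 21972937. Cells were clustered and the clusters named from marker genes fixed before the data were examined, which gave 22 named classes, each called X-like here. All fold changes are HFpEF over control, and values are mean ± SD over mice.

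The first comparison asked which cells the digests held. Capillary-like cells (general capillary or arterial endothelium-like, the cells that line most lung capillaries and the arteries that feed them) made up 24.8% ± 6.07 (SD, n = 4) of control cells and 18.2% ± 1.35 (SD, n = 4) of HFpEF cells. B cell-like cells made up 11.9% ± 6.81 of control and 22.2% ± 3.25 of HFpEF cells. NK cell-like cells, which are cytotoxic lymphocytes, were at 2.82% ± 1.37 and 4.97% ± 0.364, and venous endothelium-like cells at 1.97% ± 0.437 and 1.27% ± 0.156. In these 4 classes every HFpEF mouse lay on one side of every control mouse. With assignment by the tag ratio, capillary-like cells were at 25.6% ± 2.07 and 20.4% ± 2.72 (exact permutation p = 0.0571), where HFpEF mouse 1 (23.55%) lay above control mouse 1 (23.52%). T cell-like cells were at 6.60% ± 3.16 and 10.0% ± 1.52, and alveolar type 1-like cells, the thin cells of gas exchange, at 1.52% ± 0.533 and 0.741% ± 0.477. None of the 22 classes passed the two-sided exact permutation test after Benjamini-Hochberg adjustment, with a smallest adjusted p of 0.157. The smallest p that the 70 splits of 8 mice allow is 0.0286, and 13 of 22 classes would have to reach it for an adjusted p under 0.05. edgeR on cell counts gave a smallest adjusted p of 0.449.

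The B cell-like share rested in part on control mouse 4, where it was 1.94%, against 13.8% to 17.0% in the other control mice. In that mouse 6.37% of the B cell-like cells that the ratio of their tag counts assigned to it were called single cells by the tag caller used here, against 57.4% of its capillary-like cells. With assignment by the tag ratio, B cell-like cells made up 15.3% ± 1.16 of control and 22.3% ± 2.06 of HFpEF cells (exact permutation p = 0.0286, adjusted p = 0.21, n = 4 per group), and the control range was 14.3% to 16.9%. A cluster of 1411 low-depth cells that could not be named made up 10.9% ± 2.67 of control and 4.96% ± 0.522 of HFpEF cells. Endothelial marker RNA above 0.1 times the level in endothelial cells was found in 99.0% of its control and 98.9% of its HFpEF cells. As it was also found in 94.7% and 99.3% of pericyte-like cells, this does not name the cluster. Any endothelial cells in it are missing from the endothelial shares above. Clusters with markers of several classes were kept out of the classes by limits set after seeing the data. They held 5.68% ± 3.38 of control and 4.88% ± 0.812 of HFpEF cells (aerocyte with general capillary markers), 2.60% ± 1.64 and 2.70% ± 0.656 (alveolar macrophage with monocyte markers), and 0.208% ± 0.166 and 0.201% ± 0.0628 (B cell with capillary markers).

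**Figure D1:**
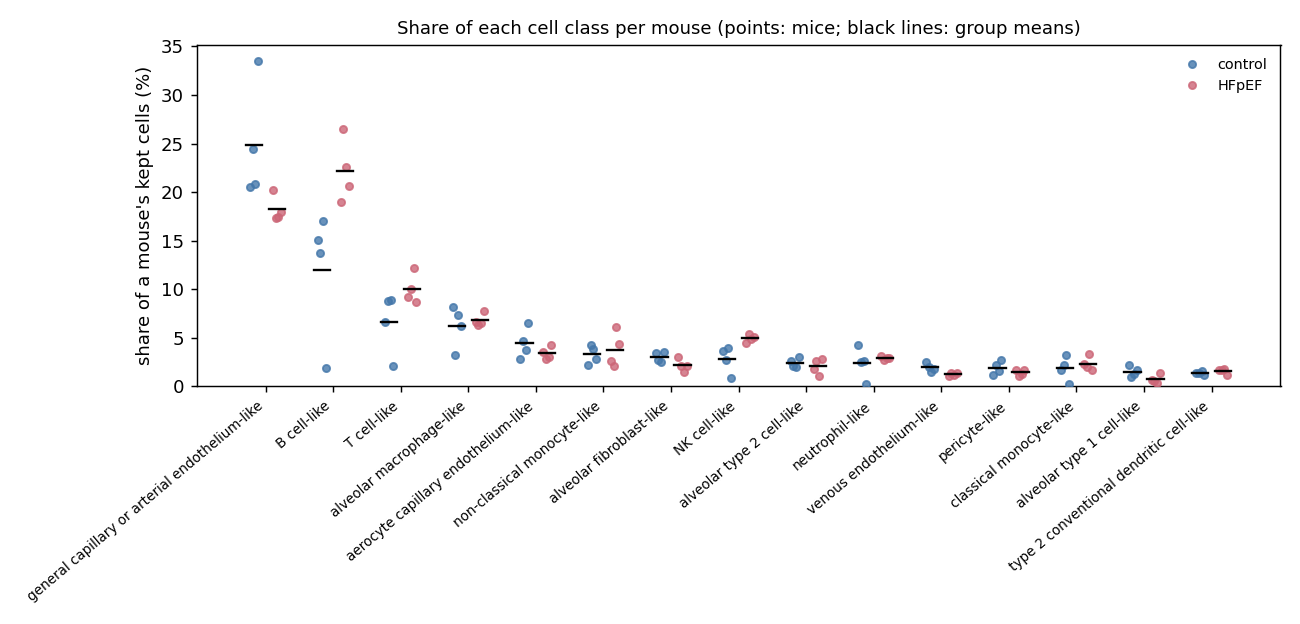
Share of each reported cell class (y axis, % of a mouse's kept cells) in control (blue) and HFpEF (red) mice, with 1 point per mouse and a black line at the group mean. B cell-like cells lay between 19.0% and 26.5% in HFpEF mice, and 1 control mouse lay at 1.94%.

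The title of the series concerns interleukin 1 beta made by myeloid cells, so Il1b (ENSMUSG00000027398), which encodes this inflammatory cytokine, was examined in each myeloid class. Neutrophil-like cells held by far the most Il1b, at 10090 ± 2090 CPM (UMI counts scaled to the TMM-adjusted total of a mouse and class) in 3 control mice and 11880 ± 1663 CPM in 4 HFpEF mice (log2 fold change 0.20, SE 0.134, edgeR adjusted p = 0.628). In alveolar macrophage-like cells Il1b was lower in HFpEF, at 65.4 ± 29.3 CPM in control and 24.1 ± 6.97 CPM in HFpEF (SD, n = 4 each, log2 fold change -1.38, SE 0.212, edgeR adjusted p = 0.000124), and every HFpEF mouse lay below every control mouse. In classical monocyte-like cells, the inflammatory blood monocytes, it was 703 ± 169 CPM in 3 control mice and 422 ± 77.6 CPM in 4 HFpEF mice (log2 fold change -0.73, SE 0.133, edgeR adjusted p = 0.00602), again without overlap. Non-classical monocyte-like cells, which patrol the vessel wall, held 642 ± 176 and 352 ± 78.0 CPM (log2 fold change -0.90, edgeR adjusted p = 0.0736), and type 2 conventional dendritic cell-like cells 400 ± 181 and 203 ± 114 CPM (log2 fold change -0.99, adjusted p = 0.689). In the sum of all cells of a mouse, Il1b was at 230 ± 93.0 CPM in control and 226 ± 14.9 CPM in HFpEF (log2 fold change -0.02, edgeR adjusted p = 0.983). Neutrophil-like cells were only 0.285% of the kept cells of control mouse 4. With assignment by the tag ratio the log2 fold change was -0.05 (edgeR adjusted p = 0.89). In classes with too few counts of Il1b for edgeR, it was at 35.1 ± 43.6 and 3.74 ± 7.08 CPM in fibroblast-like cells and 24.9 ± 27.0 and 4.82 ± 5.71 CPM in pericyte-like cells. It was at 14.4 ± 18.4 and 3.25 ± 6.14 CPM in T cell-like, 11.96 ± 20.7 and 1.47 ± 2.34 CPM in type 2-like, and 2.02 ± 1.86 and 2.48 ± 0.497 CPM in B cell-like cells. Capillary-like cells held 1.79 ± 2.38 and 2.13 ± 2.185 CPM, and aerocyte capillary endothelium-like cells 0 UMIs in both groups. The smallest exact permutation p of these classes was 0.257.

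The macrophage call was lost with coarser clusters (log2 fold change -0.42, adjusted p = 0.439). It was also lost when the cells of mixed clusters were joined to their classes (log2 fold change -0.38, adjusted p = 0.53). Those clusters had been set apart by a step chosen after seeing the data. The classical monocyte call was lost with cells thinned to 1000 UMIs (log2 fold change -0.77, adjusted p = 0.14). The non-classical monocyte fold change, not called above, was called with DESeq2 (adjusted p = 0.000842), without an expression filter (1.83e-10), with finer clusters (0.00854), with assignment by the tag ratio (0.0355), without control mouse 1 (0.0106) and without HFpEF mouse 3 (0.0294). That of dendritic cell-like cells was called without an expression filter (1.79e-05). The exact permutation test gave an adjusted p of 0.171 for the macrophage and classical monocyte classes, and 0.143 as the smallest for a difference in Il1b change between 2 myeloid classes. Its smallest possible p, 0.0286, leaves it little power after adjustment. Of the 10 pairs of classes, 6 would have to reach it for any to pass. Control mouse 4, at 109.4 CPM in alveolar macrophage-like cells, lay apart from the other control mice, and without it the log2 fold change was -1.06. Interstitial macrophage-like cells had too few cells per mouse for the test. At a minimum of 10 cells per mouse, chosen after seeing the data, they held 432 ± 241 and 223 ± 233 CPM of Il1b (log2 fold change -0.97, edgeR adjusted p = 1).

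**Figure D2:**
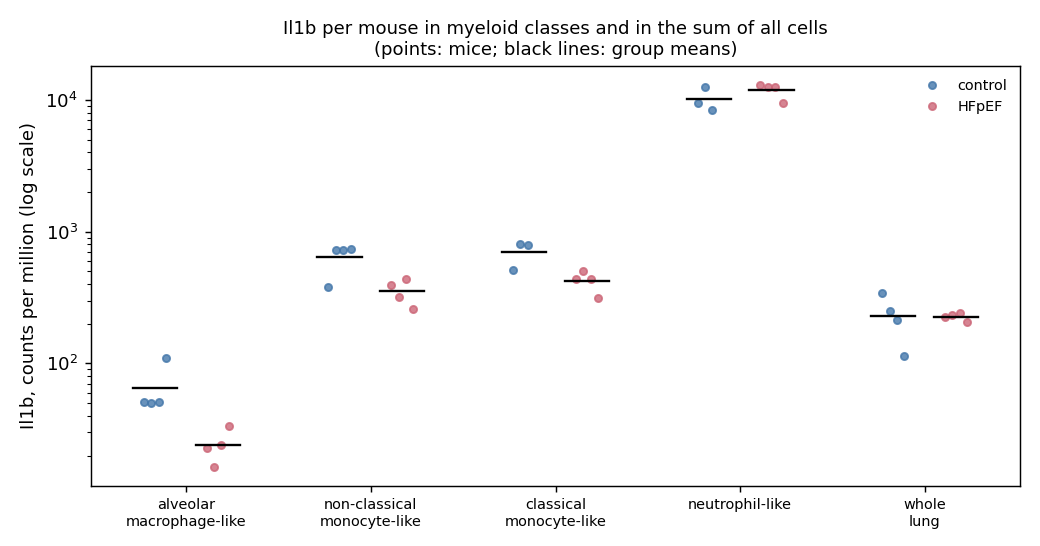
Il1b in CPM (y axis, log scale) per mouse in myeloid classes and in the sum of all cells, for control (blue) and HFpEF (red) mice, with a black line at the group mean; control classical monocyte-like and neutrophil-like cells have 3 mice. Neutrophil-like cells averaged 10090 and 11880 CPM, and alveolar macrophage-like cells 65.4 and 24.1 CPM.

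Alveolar macrophage-like cells, which clear surfactant and particles from the air spaces, expressed less of several inflammatory genes in HFpEF. Nfkbia, which encodes an inhibitor that NF-kB itself induces, fell from 211 ± 40.6 to 88.7 ± 19.3 CPM (log2 fold change -1.25, SE 0.118, edgeR adjusted p = 3.25e-08, n = 4 per group). The neutrophil chemokine gene Cxcl2 fell by 1.34 on the log2 scale, Ier3 by 1.31, Tnfaip3, which encodes a brake on NF-kB, by 0.85, and the cytokine gene Il1a by 0.92. Of the 10 measured genes of the NF-kB list 5 fell and none rose (6 adjusted over the list alone), and the list's median log2 fold change was -0.71 (camera adjusted p = 6.12e-10, and adjusted p = 0.159 with an estimated correlation). MHC class II genes, which present antigen to T cells, moved the same way. This was not particular to macrophages, as the fold change of Cd74 was negative in all 12 classes tested. Of 8 such genes measured in macrophages, 5 fell (6 adjusted over the list alone), among them Cd74 from 707 ± 166 to 341 ± 93.3 CPM and H2-Ab1 from 217 ± 56.6 to 110.1 ± 20 CPM (camera adjusted p = 1.15e-08, and adjusted p = 0.227 with an estimated correlation). The complement genes Cfb, at 81.3 ± 7.65 and 19.6 ± 3.03 CPM, and C3 fell. The complement receptor gene C5ar1 rose from 151 ± 14.1 to 193 ± 26.2 CPM, a call lost without HFpEF mouse 3 (adjusted p = 0.135) or control mouse 2 (adjusted p = 0.0617).

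Single genes that act on fatty acids were also called in these macrophages. Fabp1, a fatty acid binding protein gene that is also a marker used to name the class, rose from 645 ± 54.9 to 1055 ± 71.9 CPM (log2 fold change 0.71, SE 0.0608, edgeR adjusted p = 6.51e-09), and Acaa1b, which encodes a peroxisomal thiolase, from 111 ± 20.1 to 189 ± 8.80 CPM. Acot1, a thioesterase gene, rose from 69.4 ± 14.6 to 98.2 ± 8.05 CPM and Cpt1a, the gate of fatty acid entry into mitochondria, from 146 ± 7.37 to 181 ± 9.87 CPM. They were the 2 of 15 measured genes of the fatty acid oxidation list that rose (2 adjusted over the list alone), and none fell (camera adjusted p = 0.000625, and adjusted p = 0.155 with an estimated correlation). The Acot1 call was lost without control mouse 3 (adjusted p = 0.124) or HFpEF mouse 1 (0.0759), and the Cpt1a call without HFpEF mouse 2 (0.0848), control mouse 1 (0.0798), control mouse 4 (0.0745), HFpEF mouse 1 (0.0647) or HFpEF mouse 3 (0.054). With cells thinned to 1000 UMIs the log2 fold change of Cpt1a was -0.019. Of 15 nuclear oxidative phosphorylation genes 6 fell (12 adjusted over the list alone), such as Cox5a from 697 ± 20.5 to 585 ± 19.2 CPM (camera adjusted p = 3.85e-10, and adjusted p = 0.149 with an estimated correlation). In all 309 of 8915 genes changed, 85 higher and 224 lower. The count was 84 with coarser clusters, 55 with mixed clusters joined to their classes and 26 with cells thinned to 1000 UMIs. Both the joining and the setting apart of mixed clusters, which gave the 309, were chosen after seeing the data. Surfactant RNA of type 2 cells moved with these genes, as Sftpc was at 64.3 ± 7.57 CPM in control and 1.10 ± 1.89 CPM in HFpEF macrophages, and endothelial genes such as Cav1 (32.8 ± 7.73 and 7.56 ± 1.82 CPM) and Epas1 (23.0 ± 4.57 and 5.04 ± 2.85 CPM) were also lower. Without HFpEF mouse 4, 204 genes changed.

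Classical monocyte-like cells showed lower interferon-induced and inflammatory genes in HFpEF. Isg15, an antiviral ubiquitin-like gene, fell from 400 ± 114 CPM in 3 control mice to 185 ± 52.7 CPM in 4 HFpEF mice (log2 fold change -1.13, SE 0.173, edgeR adjusted p = 0.00244). Ifit3, another interferon-induced gene, fell from 176 ± 56.0 to 77.3 ± 32.6 CPM. Of 15 measured type I interferon genes 5 fell (15 adjusted over the list alone), with a median log2 fold change of -0.67 (camera adjusted p = 1.25e-18, and adjusted p = 0.219 with an estimated correlation). Of the 5, Ifit2 and Usp18 lost their calls without HFpEF mouse 3 (adjusted p = 0.218 for both) or HFpEF mouse 2 (0.098 and 0.142). The chemokine genes Ccl2, at 146 ± 29.5 and 63.2 ± 17.3 CPM, Ccl4 and Cxcl2 also fell, and 4 of 11 NF-kB genes fell (7 adjusted over the list alone, camera adjusted p = 2.00e-11, and adjusted p = 0.149 with an estimated correlation). In all 28 of 5420 genes changed, 3 higher and 25 lower. The count was 12 without HFpEF mouse 3, 14 without HFpEF mouse 2 and 17 without HFpEF mouse 1, 8 with DESeq2 and 2 with cells thinned to 1000 UMIs. No control mouse was left out here, as the fit held 3. Sftpc was at 20.9 ± 4.90 CPM in control and 0 UMIs in HFpEF monocytes.

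In non-classical monocyte-like cells 5 of 7397 genes changed by edgeR, while DESeq2 called 81, of which 2 were among the 5, and edgeR without an expression filter 110. Cxcl2 fell from 162 ± 59.6 to 57.2 ± 16.0 CPM and Cd14, a co-receptor for bacterial lipopolysaccharide, from 126 ± 32.8 to 54.4 ± 3.87 CPM, both with 4 mice per group (edgeR adjusted p = 0.0327 and 0.0184). Ccnd3 and Stxbp6 fell by 0.59 and 0.94 on the log2 scale, and the kinase gene Ptk2b rose by 0.65. Of 11 NF-kB genes 1 fell (7 adjusted over the list alone, camera adjusted p = 1.09e-08, and adjusted p = 0.149 with an estimated correlation). The count was 0 without HFpEF mouse 2, HFpEF mouse 4 or control mouse 4, 1 without HFpEF mouse 1, 3 without control mouse 2, 10 without HFpEF mouse 3 and 11 without control mouse 3. The Cxcl2 call held without control mouse 3 and was lost without each other mouse (adjusted p = 0.0515 to 0.186, the largest without control mouse 4). In type 2 conventional dendritic cell-like cells the surfactant gene Sftpc was the 1 gene of 5487 that changed, at 62.7 ± 18.6 CPM in control and 0 UMIs in HFpEF mice. In neutrophil-like cells edgeR found 0 changed genes of 2824 in 3 control and 4 HFpEF mice, with 315 at an unadjusted p under 0.05, while DESeq2 found 29. Without HFpEF mouse 4 edgeR found 61, with cells thinned to 1000 UMIs 31, without an expression filter 82, with assignment by the tag ratio 12, and without cells that held endothelial RNA 45.

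In capillary-like cells, genes of bone morphogenetic protein (BMP) signalling and clock genes were higher in HFpEF and antigen presentation genes were lower. Smad6 and Smad7, inhibitors that BMP signalling induces, rose from 212 ± 32.6 to 342 ± 6.95 CPM and from 265 ± 23.8 to 424 ± 40.2 CPM (log2 fold change 0.68 for both, SE 0.0796 and 0.0717, edgeR adjusted p = 3.9e-05 and 1.91e-05, n = 4 per group). Bmpr2 (ENSMUSG00000000302), the BMP receptor gene mutated in heritable pulmonary arterial hypertension, rose from 1441 ± 30.6 to 1707 ± 56.9 CPM, with no overlap between the groups, but without HFpEF mouse 4 its adjusted p was 0.0576. Of 11 BMP genes 5 rose and none fell (7 adjusted over the list alone, camera adjusted p = 3.67e-11, and adjusted p = 0.149 with an estimated correlation). Nr1d1 and Dbp, clock-controlled transcription factor genes, rose from 15.2 ± 4.38 to 44.5 ± 8.01 CPM and from 7.12 ± 0.339 to 25.3 ± 9.95 CPM, and Tef from 7.57 ± 2.14 to 18.0 ± 8.77 CPM. Arntl, the core activator of the clock, chosen after its values were seen, fell from 25.2 ± 4.07 to 14.5 ± 1.58 CPM (edgeR adjusted p = 0.00438). Of 10 clock genes 5 rose and 1 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.00104, and adjusted p = 0.293 with an estimated correlation).

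All 7 measured MHC class II genes fell in capillary-like cells (7 adjusted over the list alone), such as Cd74 from 1702 ± 470 to 813 ± 255 CPM and its regulator Ciita from 44.5 ± 10.4 to 21.2 ± 2.28 CPM (camera adjusted p = 4.23e-10, and adjusted p = 0.227 with an estimated correlation). Of 9 MHC class I genes 5 fell (9 adjusted over the list alone), such as B2m from 2484 ± 250 to 1912 ± 102 CPM and the immunoproteasome gene Psmb9 by 0.45 on the log2 scale (camera adjusted p = 8.43e-10, and adjusted p = 0.255 with an estimated correlation). Of the 5, Psmb8 and Tap1 lost their calls without HFpEF mouse 1 (adjusted p = 0.107 and 0.108), HFpEF mouse 4 (0.124 and 0.0698), control mouse 2 (0.112 and 0.0571) or control mouse 3 (0.112 and 0.0761). The cholesterol exporter gene Abca1, Scd2 and Apoe were the 3 of 8 targets of the sterol receptor LXR that fell (6 adjusted over the list alone, camera adjusted p = 0.000172, and adjusted p = 0.155 with an estimated correlation). Ucp2, a mitochondrial carrier gene, rose from 247 ± 22.9 to 396 ± 32.5 CPM, and Cx3cr1, a chemokine receptor gene typical of monocytes, fell from 62.2 ± 16.5 to 23.4 ± 2.62 CPM. The inducible chaperone genes Hspa1a and Hspa1b fell, to 6.76 ± 1.51 and 1.87 ± 0.230 CPM, from 40.8 ± 48.5 and 20.5 ± 26.7 CPM in control mice, where control mouse 1 stood apart at 113 and 60.5 CPM. Calls for Hspa1a, Hspa1b and Abca1 were lost without any 1 HFpEF mouse (largest adjusted p = 0.0976, 0.0891 and 0.129, the first without HFpEF mouse 3, the second without HFpEF mouse 1, the last without HFpEF mouse 3). That for Apoe was lost without control mouse 3 (0.0663), control mouse 2 (0.0641) or HFpEF mouse 1 (0.0563). In all 395 of 10580 genes changed, 118 higher and 277 lower. The alveolar type 1 marker Ager was at 25.9 ± 5.04 and 7.17 ± 1.28 CPM in these cells. The count was 241 without HFpEF mouse 1, 241 without HFpEF mouse 4 and 261 without HFpEF mouse 3.

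**Figure D3:**
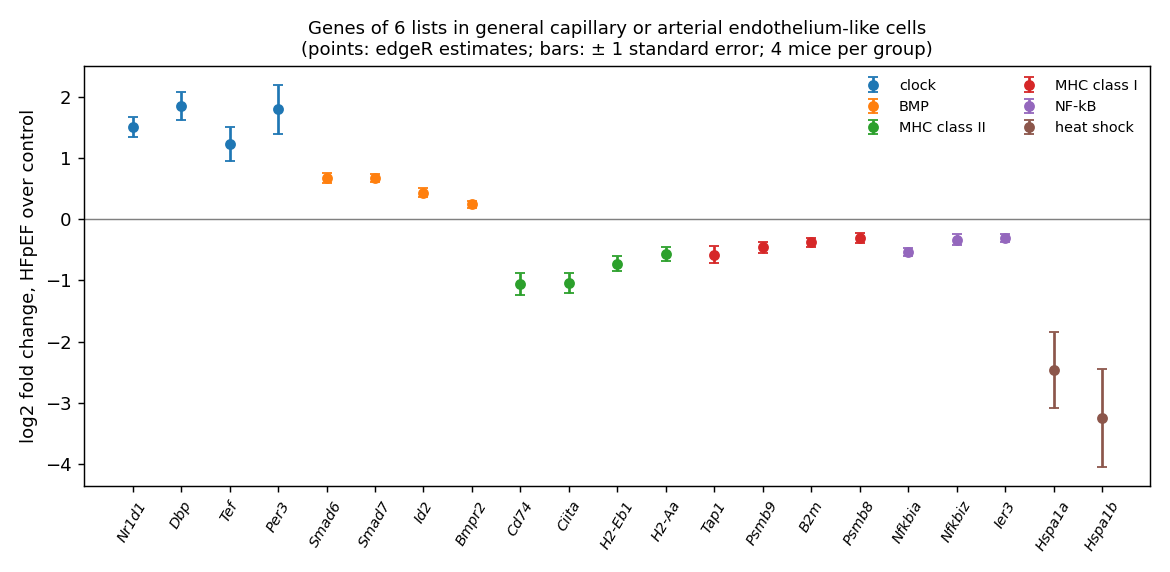
Log2 fold change of HFpEF over control (y axis) of genes from 6 lists in capillary-like cells (4 mice per group). Points are edgeR estimates, and bars are ± 1 standard error derived from the F statistic. Nr1d1 lay at 1.51 and Smad6 at 0.68, and Cd74 lay at -1.06.

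Aerocyte capillary endothelium-like cells, the wide capillary cells specialised for gas exchange, had 42 changed genes of 6932, 12 higher and 30 lower. Id1, a target of BMP signalling, rose from 684 ± 76.4 to 984 ± 97.9 CPM (log2 fold change 0.51, SE 0.077, edgeR adjusted p = 0.000101, n = 4 per group) and was the 1 of 9 BMP genes that did (3 adjusted over the list alone, camera adjusted p = 0.000148, and adjusted p = 0.183 with an estimated correlation). Nr1d1 rose from 7.22 ± 4.61 to 31.3 ± 11.8 CPM. Hspa1a fell from 45.7 ± 21.5 to 6.41 ± 5.56 CPM, and the interferon-inducible GTPase gene Ifi47 from 109 ± 17.5 to 59.5 ± 10.4 CPM. The leukocyte adhesion gene Icam1 fell from 516 ± 58.3 to 367 ± 41.8 CPM. Without HFpEF mouse 4 the adjusted p of Nr1d1, Ifi47 and Icam1 was 0.0616. The count was 5 without HFpEF mouse 4, 13 without HFpEF mouse 1, 18 without control mouse 2 and 24 without control mouse 3. It was 175 with coarser clusters, 6 with DESeq2 and 1 with cells thinned to 1000 UMIs.

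Alveolar fibroblast-like and pericyte-like cells, which support the alveolar wall and wrap its capillaries, had few changed genes. Endothelial marker RNA above 0.1 times the level in endothelial cells was found in 79.3% of control and 77.5% of HFpEF fibroblast-like cells and in 94.7% and 99.3% of pericyte-like cells. General capillary markers summed to 4084 ± 426 and 4463 ± 279 CPM in fibroblast-like and 5850 ± 521 and 5989 ± 392 CPM in pericyte-like cells. Nr1d1 rose from 49.3 ± 7.60 to 111 ± 5.85 CPM in fibroblasts (edgeR adjusted p = 0.00434) and from 15.4 ± 4.34 to 56.3 ± 13.7 CPM in pericytes (edgeR adjusted p = 0.00338). Hspa1a fell from 69.3 ± 18.9 to 20.2 ± 7.16 CPM and from 123 ± 24.4 to 23.4 ± 15.7 CPM. The elastin gene Eln fell in fibroblasts from 278 ± 85.9 to 101 ± 35.2 CPM (log2 fold change -1.48, SE 0.235, edgeR adjusted p = 0.0234, n = 4 per group) and was the 1 of 17 matrix genes that did (4 adjusted over the list alone, camera adjusted p = 0.000682, and adjusted p = 0.257 with an estimated correlation). Zbtb16, a glucocorticoid-induced gene, fell in fibroblasts from 249 ± 43.7 to 103 ± 25.3 CPM, and Klf2, a gene induced by shear stress, fell in pericytes from 1716 ± 141 to 1189 ± 139 CPM. The Eln call was lost without HFpEF mouse 1 (adjusted p = 0.203), HFpEF mouse 4 (0.112), HFpEF mouse 3 (0.101), control mouse 2 (0.0798) or control mouse 4 (0.0627). That of Hspa1a in fibroblasts was lost without HFpEF mouse 3 (0.0771), control mouse 2 (0.0665) or HFpEF mouse 4 (0.0504), and that of Zbtb16 without HFpEF mouse 1 (0.116). The Klf2 call was lost without HFpEF mouse 3 (0.106), HFpEF mouse 4 (0.101), HFpEF mouse 2 (0.0589), control mouse 3 (0.053) or control mouse 2 (0.0522). In all 9 of 8980 genes changed in fibroblasts and 8 of 8580 in pericytes. The fibroblast count was 2 without HFpEF mouse 1, HFpEF mouse 3 or control mouse 2, 3 without HFpEF mouse 4 and 28 without HFpEF mouse 2. The pericyte count was 2 without HFpEF mouse 3, 3 without HFpEF mouse 1, 4 without HFpEF mouse 4 or control mouse 3 and 14 without control mouse 4.

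Alveolar type 2-like cells, which make surfactant, had 846 changed genes of 7651, 523 higher and 323 lower. Surfactant genes, some of which also name the class, were lower in HFpEF. Sftpc fell from 229200 ± 25280 to 150800 ± 26860 CPM (log2 fold change -0.59, SE 0.123, edgeR adjusted p = 0.00586, n = 4 per group), Sftpa1 from 21880 ± 1979 to 14340 ± 1858 CPM, and 6 of 10 surfactant genes fell (7 adjusted over the list alone, camera adjusted p = 1.79e-06, and adjusted p = 0.348 with an estimated correlation). Scd1, a fatty acid desaturase gene, fell from 2395 ± 332 to 1229 ± 340 CPM and was 1 of the 3 of 7 fatty acid synthesis genes that did (5 adjusted over the list alone, camera adjusted p = 0.000206, and adjusted p = 0.366 with an estimated correlation). Of 7 MHC class II genes 5 fell (7 adjusted over the list alone, camera adjusted p = 6.37e-06, and adjusted p = 0.227 with an estimated correlation). Of the 5, H2-DMa and H2-Eb1 lost their calls without HFpEF mouse 1 (adjusted p = 0.111 and 0.0734), HFpEF mouse 4 (0.0706 and 0.0737), control mouse 1 (0.0686 and 0.0594) or control mouse 3 (0.105 and 0.0903). Areg, an epidermal growth factor family gene, fell from 152 ± 46.1 to 52.1 ± 13.9 CPM.

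The genes that rose in type 2-like cells included many of the endothelium, such as the receptor genes Kdr, from 46.7 ± 16.6 to 193 ± 75.9 CPM, and Tek, from 39.2 ± 15.7 to 129 ± 15.2 CPM, and the clotting factor gene Vwf, from 14.9 ± 11.7 to 62.0 ± 27.2 CPM. General capillary markers summed to 557 ± 133 CPM in control and 1474 ± 257 CPM in HFpEF type 2-like cells (exact permutation p = 0.0286, n = 4 per group). Endothelial marker RNA above 0.1 times the level in endothelial cells was found in 16.7% of 215 control and 31.6% of 177 HFpEF type 2-like cells. Without those cells, a step chosen after seeing the data that left 4 control and 3 HFpEF mice, 2 genes changed by edgeR, Cebpd and Irx1, both chosen after their values were seen, which fell by 1.14 and 1.05 on the log2 scale (adjusted p = 0.0223 and 0.0133). Of the 523 raised genes 200 were then still measured, with a median log2 fold change of 0.104, against 1.283 with all cells. The 322 measured genes of the 323 lower ones had a median of -0.27, against -0.61 with all cells. The count was 502 without HFpEF mouse 1, 315 with Scrublet doublets kept and 8 with cells thinned to 1000 UMIs.

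**Figure D4:**
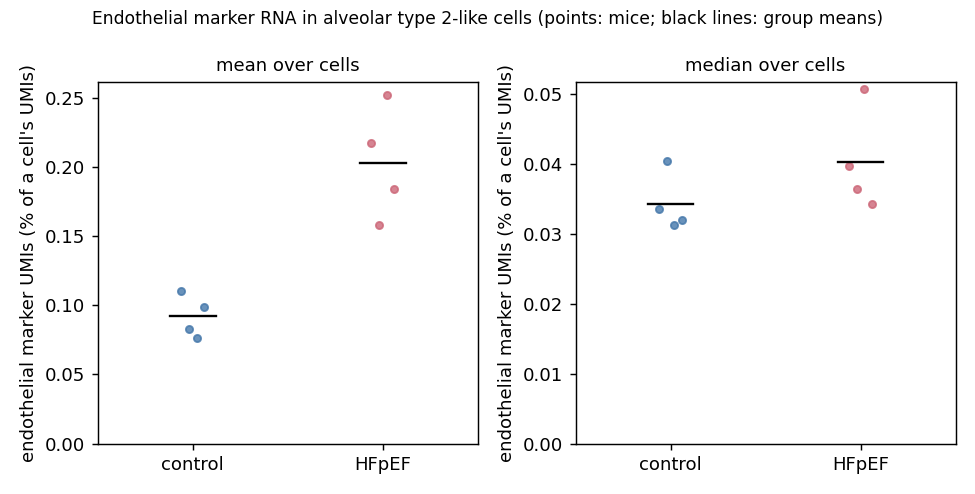
Endothelial marker UMIs (y axis, % of a cell's UMIs) in alveolar type 2-like cells, as the mean over cells (left) and the median over cells (right), with 1 point per mouse for control (blue) and HFpEF (red) and a black line at the group mean. The mean share was 0.092% in control and 0.203% in HFpEF, and the median 0.0343% and 0.0402%.

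In B cell-like cells 188 of 8250 genes changed, 30 higher and 158 lower. The count was 5, all lower, when a mixed cluster was joined to the class, 94 with DESeq2 and 95 with cells thinned to 1000 UMIs. Both the joining and the setting apart of that cluster, which gave the 188, were chosen after seeing the data. Of 8 heat shock genes 5 fell (5 adjusted over the list alone), such as Hspa1b from 14 ± 5.09 to 0.998 ± 1.01 CPM and Dnajb1 from 118 ± 13.9 to 79.0 ± 7.28 CPM (n = 4 per group, camera adjusted p = 3.77e-09, and adjusted p = 0.155 with an estimated correlation). Of 12 immediate early genes, which respond within minutes to stimulation, 4 fell (9 adjusted over the list alone), such as Nr4a1, a gene induced by antigen receptor signals, from 156 ± 8.44 to 93.5 ± 11 CPM (camera adjusted p = 4.05e-09, and adjusted p = 0.149 with an estimated correlation). The other 3, Atf3, Dusp1 and Junb, lost their calls without HFpEF mouse 3 (adjusted p = 0.135, 0.055 and 0.0606). Dusp1 and Junb lost them without HFpEF mouse 4 (0.0589 and 0.129), and Atf3 and Junb without control mouse 4 (0.0547 and 0.117). General capillary markers moved with the lower genes, at 26.8 ± 14.8 CPM in control and 1.95 ± 1.98 CPM in HFpEF B cell-like cells, and endothelial genes such as Calcrl, Ramp2 and Hpgd were among the lower ones. The count was 113 without control mouse 1.

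In T cell-like cells 32 of 7439 genes changed, 14 higher and 18 lower. Il7r, the interleukin 7 receptor gene that naive and memory T cells depend on, rose from 571 ± 72.5 to 831 ± 69.8 CPM, and Klf2, which keeps T cells in circulation, from 1062 ± 120 to 1487 ± 121 CPM (edgeR adjusted p = 0.00534 and 0.00822, n = 4 per group), calls lost without HFpEF mouse 4 (adjusted p = 0.0594 for both) and, for Klf2, without HFpEF mouse 2 (0.0594). Il12rb2, a receptor gene of type 1 helper cells, fell from 44.4 ± 18.0 to 15.4 ± 2.45 CPM. Of 87 ribosomal protein genes Rpl12, Rpl5 and Rps25 rose (7 adjusted over the list alone, camera adjusted p = 4.06e-25, and adjusted p = 0.348 with an estimated correlation). These 3 calls were lost without HFpEF mouse 4 (adjusted p = 0.144, 0.141 and 0.119), HFpEF mouse 2 (0.119, 0.121 and 0.0808) or HFpEF mouse 1 (0.104, 0.0779 and 0.0545). They were also lost without control mouse 2 (0.119, 0.102 and 0.0744) or control mouse 3 (0.0874, 0.0756 and 0.077). Those of Rpl12 and Rpl5 were lost without control mouse 1 (0.0794 for both). General capillary markers were at 69.3 ± 28.7 and 18.7 ± 7.23 CPM. The count was 5 without HFpEF mouse 4, 9 without HFpEF mouse 2, 11 without control mouse 2, 14 without control mouse 3, 18 without HFpEF mouse 1 and 20 without control mouse 1. It was 150 with Scrublet doublets kept and 14 without cells that held endothelial RNA.

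The sum of all kept cells of a mouse, which mixes composition with expression, asked what an undivided lung sample would show. Of 15706 genes 24 changed by edgeR, 2 higher and 22 lower. DESeq2 called 648, 221 higher and 427 lower, and with assignment by the tag ratio edgeR called 332, 134 higher and 198 lower. Nr1d1 rose from 12.8 ± 2.46 to 26.5 ± 1.76 CPM, and Hspa1a, Isg15 and the matricellular gene Ccn2 fell, from 37.1 ± 14.1 to 7.75 ± 1.70 CPM, from 100.4 ± 8.85 to 60.9 ± 6.41 CPM and from 22.7 ± 4.05 to 9.16 ± 1.51 CPM (edgeR adjusted p = 0.0442 each, n = 4 per group). Cebpd, an inducible transcription factor gene, fell from 266 ± 40.8 to 140 ± 13.1 CPM. Of 16 type I interferon genes Isg15 and Rtp4 fell (12 adjusted over the list alone, camera adjusted p = 4.23e-10, and adjusted p = 0.219 with an estimated correlation). Both calls were lost without each mouse but control mice 1 and 4 (largest adjusted p = 0.157 and 0.139). None of the calls for Nr1d1, Hspa1a, Isg15, Ccn2 and Cebpd held without HFpEF mouse 4, where the largest adjusted p was 0.157. The count was 1 without HFpEF mouse 1, HFpEF mouse 2 or control mouse 2, 2 without HFpEF mouse 3 or control mouse 3, 3 without HFpEF mouse 4, 11 without control mouse 4 and 149 without control mouse 1.

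Over all classes and the whole lung, 141 of 325 pairs of a gene list and a class passed camera with the preset correlation. None of these calls held with an estimated correlation, where the smallest adjusted p was 0.149. Each of the 34 other splits of the mice passed 21 to 107 pairs at the preset correlation. fry, which tests whether a list's genes move one way, passed 23 pairs.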

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

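The tests of explanations and the splits of mice in this part were chosen after the results were seen; the rule that names differences between classes was fixed before the data were examined.

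Control mouse 4 had few blood leukocytes among its assigned cells. Its B cell-like share was 14.347% with assignment by the ratio of tag counts, against 14.6% to 16.9% in the other control mice, and 1.94% with the tag caller used in the report. Its leukocyte share by that rule was 37.782%, against 39.2% to 42.8%, which argues against a lung with far fewer leukocytes. The median tag count of its B cell-like cells was 173.5, under the limit of 371 that the caller set. A tag limit above the counts of small cells may therefore account for most of the low share.

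Endothelial genes were higher in HFpEF type 2-like cells. The mean endothelial share of UMIs per cell was 2.2 times that of control (exact permutation p = 0.0286, n = 4 per group), and the median 1.17 times (p = 0.229). Each cell making more endothelial RNA would raise the median as much as the mean, which the tables argue against. Without surfactant genes the raised genes had a median log2 fold change of 1.292, against 1.283 with them. TMM scaling already limits the weight of a few abundant genes, so that this refit cannot decide on scaling by a lower surfactant share. Endothelial RNA in a subset of cells, from attached cells or uncaught doublets, may account for the rise, and whether the subset differs between libraries or lungs stays open.

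Il1b was lower in HFpEF alveolar macrophage-like cells. RNA of monocytes and neutrophils in this class is argued against, as the median marker of these sources would bring -3.28% of the fall, although Treml4 and Ace would bring 15.5 and 12.9 CPM of the 41.3 CPM and Fn1 198.2 CPM, a gene that control macrophages held at 601 CPM and monocytes at 895 CPM (Ly6c2 at 3.06 and 1641 CPM). A weaker dissociation response in the HFpEF library could not be excluded, with a lower quartile of -0.228 among log2 fold changes of 12 immediate early genes, against a median of -0.71 for NF-kB genes, because 2 of the 12, Dusp1 and Atf3, chosen after their values were seen, were called lower (-0.398 and -0.353). A difference between the 2 libraries, such as in stray Il1b RNA, cannot be told apart from the group, as there was 1 library per group. Il1b was at 35.1 ± 43.6 and 3.74 ± 7.08 CPM in fibroblast-like and 24.9 ± 27.0 and 4.82 ± 5.71 CPM in pericyte-like cells. In capillary-like cells it was at 1.79 ± 2.38 and 2.13 ± 2.185 CPM. The diet and drug stay open as an untested biological explanation.

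The mice were also split in the other ways that keep the group sizes, 35 splits in all. No other split gave as many changed genes as the real one (1 of 35) in alveolar macrophage-like cells (309, highest other 9), classical monocyte-like cells (28, 8), B cell-like cells (188, 6), capillary-like cells (395, 9), aerocyte-like cells (42, 18), type 2-like cells (846, 2), fibroblast-like cells (9, 4) and the whole lung (24, 0). The same held for the 141 pairs of list and class (107). A share of 1 in 35 is the smallest that the splits allow and was not adjusted over the classes, so that chance is not excluded. The other splits mix the groups, and a real difference then adds to the spread within them and can lower their counts. Each other split still passed 21 to 107 of the 325 pairs, so that many pairs pass camera at the preset correlation under splits other than the real one. Some of those splits keep most mice of a group together and carry part of the real difference. The range is therefore not a count for no difference between groups. At least 1 other split gave as many changed genes in non-classical monocyte-like cells (2 of 35 splits with the real one, 5 against 6), T cell-like cells (2 of 35, 32 against 71), pericyte-like cells (2 of 35, 8 against 16) and dendritic cell-like cells (7 of 35, 1 against 4). There the splits give no evidence against chance. For neutrophil-like cells the real count of 0 fixes the outcome, so that the splits say nothing on chance there. In neutrophil-like cells 2 other splits called 113 and 104 genes, against 0, which points to a structure among those mice that was not tested.

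Of 581 sets of 4 mice, 44 (7.57%) had a mouse far from the others by Dixon's test, where chance gives about 1 in 20. In alveolar macrophage-like cells these were, in CPM, Il1b 109.4, Hpgd 49.3 and C3 61.3 (control mice 4, 2 and 2), Cox6c 610.3 and Rpl9 1354 (control mouse 1), Il18 528.6 (HFpEF mouse 1), Sftpc 3.92 (HFpEF mouse 2), and Ier3 43.1, C5ar1 232, Tsc22d3 71.4 and Rpl10a 941 (HFpEF mouse 3). In non-classical monocyte-like cells they were Il1b 379 (control mouse 1), Casp1 63.4 (HFpEF mouse 3) and Ccnd3 381 (HFpEF mouse 2), and in neutrophil-like cells Il1b 9413 and Il1rn 101.8 (HFpEF mouse 4). In B cell-like cells they were Faim 32.9 (control mouse 3), Gsn 40.1 (control mouse 2), Selenop 92.4, Ramp2 87.3 and Dnaja1 282 (control mouse 4), Prpf31 43.7 (HFpEF mouse 2), Snhg9 2.82 (HFpEF mouse 3) and Ramp2 3.94 (HFpEF mouse 1). In T cell-like cells they were Klf2 885 (control mouse 4) and Rpl5 1514 (HFpEF mouse 3).

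In capillary-like cells the mice that stood apart had, in CPM, Inpp4b 6.39 (control mouse 2), Abca1 53.7, Hspa1a 113, Hspa1b 60.5 and Tef 10.7 (control mouse 1), AY036118 459, Smad6 353 and Nrp1 598 (HFpEF mouse 4) and Nup210l 10.4 (HFpEF mouse 2), and in aerocyte-like cells Hspa1a 77.8 (control mouse 2). In type 2-like cells they had Stard9 13.2 (control mouse 1), Lrg1 363 and Acvrl1 44.5 (control mouse 2), Cav1 108 (control mouse 4), and H2-Aa 741 and Gclc 114 (HFpEF mouse 3). Eln was 154 in fibroblast-like and Hspa1b 37.7 in pericyte-like cells of HFpEF mouse 2.

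Pairs of classes in which the naming rule takes the same gene with opposite calls gave 4 genes in 5 pairs. Other genes, and these genes in further classes, were also called both ways, such as Ramp2 (higher in 2 and lower in 3 classes), Klf2 (3 and 2) and Eln (2 and 1). As the pairs were taken because of these calls, the permutation test of the differences adds no evidence, and the differences count as not tested. B2m rose in type 2-like cells and fell in capillary-like and aerocyte-like cells, with changes 0.8 and 0.735 apart on the log2 scale. Cav1 rose in type 2-like and fell in alveolar macrophage-like cells (3.383 apart), and Eln rose in type 2-like and fell in fibroblast-like cells (3.868 apart). Klf2 rose in T cell-like and fell in pericyte-like cells (1.021 apart). Both B2m differences turned negative without cells that held endothelial RNA, at -0.17 and -0.23, and that of Cav1 was 1.33.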

How the results depend on the processing

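Joining mixed clusters, leaving out cells with endothelial RNA, the minimum of 10 cells and fry in either direction were chosen after the results were seen. Joining undoes the setting apart of mixed clusters, itself a step set after seeing the data. Of the values that answer a comparison, 764 stayed the same, 14 lost a call, 8 gained one, 40 turned sign and 119 moved. Counts of changed genes or list pairs stayed the same within a set ratio of the count in the report, and moved beyond it. Other values stayed the same if they kept their direction and side of the threshold, also where nothing was called. For single named genes 4911 kept their direction and side, 1043 lost a call, 3 gained one and 74 turned sign. Both sets of totals include refits that could not differ from the report, such as the whole lung under other cluster resolutions. The totals of values that stayed the same therefore overstate how stable the results were. The cause was not tested, except that thinning leaves fewer UMIs and leaving out a mouse fewer samples. At a minimum of 1000 UMIs per cell all 50 values that answer a comparison and all 281 of single genes stayed the same by these rules. Classes with too few mice under a setting, and genes under its expression filter, gave no value there. Neutrophil-like sums held 145763 to 275973 UMIs per mouse, where 51% of simulated 2-fold changes were recovered, against 91% in capillary-like cells. Thinning gave more calls in neutrophil-like cells, so that depth was not shown to limit their count. RLE and DESeq2 scaling moved the median of all genes by at most 0.015 on the log2 scale. Of the 325 pairs of list and class, 141 passed camera with a preset and 0 camera with an estimated correlation (smallest adjusted p = 0.149; unadjusted p under 0.05 for 63), while fry passed 23 and fry in either direction 109. In the report edgeR called 188 in B cell-like, 32 in T cell-like, 42 in aerocyte-like, 9 in fibroblast-like, 309 in alveolar macrophage-like, 846 in type 2-like, 28 in classical monocyte-like, 395 in capillary-like, 0 in neutrophil-like, 5 in non-classical monocyte-like, 8 in pericyte-like, 1 in dendritic cell-like and 24 in the whole lung. Names with a colon are those of the results table.

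Tag numbers were not given as pairing mice. Deviations of same-numbered mice had correlations of 0.301, -0.01, 0.113 and 0.152, and 2 of the 4 numbers correlated best with their own. With the tag number as a replicate block, changed genes numbered 313 in B cell-like, 12 in T cell-like, 20 in aerocyte-like, 101 in classical monocyte-like, 175 in neutrophil-like, 93 in non-classical monocyte-like, 25 in pericyte-like, 3 in dendritic cell-like and 1 in the whole lung. Il1b had a log2 fold change of -0.89 in non-classical monocyte-like (adjusted p = 0.012) and 0.085 in the whole lung (adjusted p = 0.869). Single genes that turned sign had log2 fold changes of -0.069 for Il1r1 in aerocyte-like and 0.086 for Il1rn in neutrophil-like.

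With cluster resolution 0.5, changed genes numbered 175 in aerocyte-like, 84 in alveolar macrophage-like and 0 in non-classical monocyte-like. The log2 fold change of Il1b was -0.42 in alveolar macrophage-like (adjusted p = 0.439). Differences between classes were 0.45 for Il1b in alveolar macrophage-like minus non-classical monocyte-like. The sign of single genes turned, with log2 fold changes of 0.062 for Il1a in aerocyte-like, -0.13 for Il1r1 in aerocyte-like and -0.092 for Xab2 in aerocyte-like.

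With mixed clusters joined to classes, changed genes numbered 5 in B cell-like, 178 in aerocyte-like and 55 in alveolar macrophage-like. Il1b had a log2 fold change of -0.38 in alveolar macrophage-like (adjusted p = 0.53). Between classes the differences were 0.41 for Il1b in alveolar macrophage-like minus classical monocyte-like, 0.51 for Il1b in alveolar macrophage-like minus non-classical monocyte-like and 0.71 for Il1b in alveolar macrophage-like minus dendritic cell-like. Single genes that turned sign had log2 fold changes of 0.060 for Il1a in aerocyte-like, -0.12 for Il1r1 in aerocyte-like and -0.067 for named gene Xab2: aerocyte capillary endothelium.

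With cells thinned to 1000 UMIs, changed genes numbered 95 in B cell-like, 18 in T cell-like, 1 in aerocyte-like, 1 in fibroblast-like, 26 in alveolar macrophage-like, 8 in type 2-like, 2 in classical monocyte-like, 104 in capillary-like, 31 in neutrophil-like, 0 in non-classical monocyte-like, 0 in pericyte-like and 0 in dendritic cell-like. For Il1b the log2 fold change was -0.77 in classical monocyte-like (adjusted p = 0.14) and 0.25 in the whole lung (adjusted p = 0.739). Differences between classes were 0.27 for B2m in type 2-like minus aerocyte-like, 0.17 for B2m in type 2-like minus capillary-like, 4.02 for difference between classes: Cav1, alveolar type 2 cell minus alveolar macrophage, 4.56 for Eln in type 2-like minus fibroblast-like, 0.11 for Il1b in alveolar macrophage-like minus classical monocyte-like, 0.10 for Il1b in alveolar macrophage-like minus non-classical monocyte-like, -0.026 for Il1b in classical monocyte-like minus non-classical monocyte-like, -0.35 for Il1b in classical monocyte-like minus dendritic cell-like, -0.40 for Il1b in non-classical monocyte-like minus dendritic cell-like and 1.19 for Klf2 in T cell-like minus pericyte-like. Among single genes the sign turned for log2 fold changes of 0.0093 for named gene Cox6c: alveolar macrophage, -0.019 for Cpt1a in alveolar macrophage-like, 0.035 for Il1r1 in capillary-like, 0.094 for Il1rn in alveolar macrophage-like, 0.043 for Il1rn in neutrophil-like, 0.20 for Nlrp3 in alveolar macrophage-like and 0.012 for Uqcrq in type 2-like.

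With DESeq2, changed genes numbered 94 in B cell-like, 6 in aerocyte-like, 30 in fibroblast-like, 8 in classical monocyte-like, 263 in capillary-like, 29 in neutrophil-like, 81 in non-classical monocyte-like, 22 in pericyte-like, 4 in dendritic cell-like and 648 in the whole lung. The log2 fold change of Il1b was -0.89 in non-classical monocyte-like (adjusted p = 0.000842). The sign of single genes turned, with log2 fold changes of 0.0065 for Il18 in non-classical monocyte-like, -0.0091 for named gene Il1r1: aerocyte capillary endothelium and 0.0046 for Il1r1 in capillary-like.

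With cluster resolution 2, changed genes numbered 52 in T cell-like, 23 in aerocyte-like and 8 in non-classical monocyte-like. Il1b had a log2 fold change of -0.85 in non-classical monocyte-like (adjusted p = 0.00854). Single genes that turned sign had log2 fold changes of 0.0084 for Casp1 in alveolar macrophage-like, -0.014 for Casp1 in capillary-like, -0.19 for Il18 in dendritic cell-like and 0.0079 for Il1r1 in capillary-like.

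With no expression filter, changed genes numbered 366 in B cell-like, 196 in T cell-like, 76 in aerocyte-like, 215 in fibroblast-like, 488 in alveolar macrophage-like, 1270 in type 2-like, 120 in classical monocyte-like, 702 in capillary-like, 82 in neutrophil-like, 110 in non-classical monocyte-like, 181 in pericyte-like and 88 in dendritic cell-like. For Il1b the log2 fold change was -0.88 in non-classical monocyte-like (adjusted p = 1.83e-10) and -0.98 in dendritic cell-like (adjusted p = 1.79e-05). Among single genes the sign turned for log2 fold changes of 0.011 for Il18 in non-classical monocyte-like and 0.0043 for Il1rn in neutrophil-like.

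With assignment by the tag ratio, changed genes numbered 293 in B cell-like, 18 in fibroblast-like, 1347 in type 2-like, 12 in neutrophil-like, 10 in non-classical monocyte-like, 18 in pericyte-like and 332 in the whole lung. The log2 fold change of Il1b was -0.97 in non-classical monocyte-like (adjusted p = 0.0355). Between classes the differences were -0.67 for Il1b in classical monocyte-like minus dendritic cell-like and -0.71 for Il1b in non-classical monocyte-like minus dendritic cell-like. The sign of single genes turned, with log2 fold changes of 0.0045 for Casp1 in alveolar macrophage-like, -0.26 for Casp1 in capillary-like, 0.043 for Il18 in non-classical monocyte-like and 0.12 for Il1r1 in capillary-like.

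With Scrublet doublets kept, changed genes numbered 150 in T cell-like, 315 in type 2-like, 16 in classical monocyte-like, 5 in pericyte-like and 15 in the whole lung. For Il1b the log2 fold change was 0.011 in the whole lung (adjusted p = 0.99). Differences between classes were 0.44 for B2m in type 2-like minus aerocyte-like and -0.026 for Il1b in classical monocyte-like minus non-classical monocyte-like. Among single genes the sign turned for log2 fold changes of -0.070 for Casp1 in capillary-like, -0.049 for Ifi27l2a in type 2-like, -0.087 for named gene Il1r1: aerocyte capillary endothelium, 0.0032 for Il1r1 in capillary-like and -0.16 for Il1r2 in dendritic cell-like.

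Without cells that held endothelial RNA, changed genes numbered 14 in T cell-like, 2 in type 2-like and 45 in neutrophil-like. The log2 fold change of Il1b was 0.0075 in the whole lung (adjusted p = 0.992). Between classes the differences were -0.23 for B2m in type 2-like minus aerocyte-like, -0.17 for B2m in type 2-like minus capillary-like and 1.33 for Cav1 in type 2-like minus alveolar macrophage-like. The sign of single genes turned, with log2 fold changes of -0.52 for B2m in type 2-like, -0.58 for Bst2 in type 2-like, 0.0034 for Casp1 in alveolar macrophage-like and 0.14 for Nlrp3 in dendritic cell-like.

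At a mitochondrial limit of 5%, changed genes numbered 15 in fibroblast-like, 1 in neutrophil-like and 14 in the whole lung. Il1b had a log2 fold change of 0.0086 in the whole lung (adjusted p = 0.99). Differences between classes were 0.013 for Il1b in alveolar macrophage-like minus dendritic cell-like. Single genes that turned sign had log2 fold changes of 0.031 for Casp1 in alveolar macrophage-like, -0.0084 for named gene Casp1: general capillary or arterial endothelium, -0.0048 for named gene Il1r1: aerocyte capillary endothelium and 0.081 for Nlrp3 in dendritic cell-like.

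As shares within immune, endothelial, epithelial or mesenchymal cells, HFpEF minus control shares in percentage points turned to 0.81 for aerocyte-like, -7.55 for class shares: alveolar macrophage, 11.71 for class shares: alveolar type 2 cell, -0.24 for classical monocyte-like, -0.48 for neutrophil-like, -3.54 for class shares: non-classical monocyte, 2.68 for pericyte-like and -1.26 for dendritic cell-like.

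At a mitochondrial limit of 20%, changed genes numbered 21 in T cell-like. Among single genes the sign turned for log2 fold changes of 0.020 for Casp1 in alveolar macrophage-like, 0.0050 for Il1r1 in capillary-like and 0.0066 for Il1rn in alveolar macrophage-like.

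At a minimum of 50 cells per mouse, changed genes numbered 0 in non-classical monocyte-like. The sign of single genes turned, with log2 fold changes of 0.014 for Il18 in non-classical monocyte-like.

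With RLE scaling, single genes that turned sign had log2 fold changes of 0.0036 for named gene Il1r1: general capillary or arterial endothelium.

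When 1 mouse at a time was left out, changed genes ranged over 113 to 172 in B cell-like (without control mouse 1 and HFpEF mouse 2), 5 to 44 in T cell-like (without HFpEF mouse 4 and HFpEF mouse 3), 5 to 37 in aerocyte-like (without HFpEF mouse 4 and HFpEF mouse 2), 2 to 28 in fibroblast-like (without HFpEF mouse 1 and HFpEF mouse 2), 204 to 292 in alveolar macrophage-like (without HFpEF mouse 4 and control mouse 2), 502 to 1086 in type 2-like (without HFpEF mouse 1 and HFpEF mouse 2), 12 to 28 in classical monocyte-like (without HFpEF mouse 3 and control mouse 4, which was not in this fit), 241 to 409 in capillary-like (without HFpEF mouse 1 and control mouse 4), 0 to 61 in neutrophil-like (without HFpEF mouse 1 and HFpEF mouse 4), 0 to 11 in non-classical monocyte-like (without HFpEF mouse 2 and control mouse 3), 2 to 14 in pericyte-like (without HFpEF mouse 3 and control mouse 4) and 1 to 149 in the whole lung (without HFpEF mouse 1 and control mouse 1). Il1b fold changes on the log2 scale ranged over -1.05 to -0.76 in non-classical monocyte-like and -0.24 to 0.23 in the whole lung. Shares in percentage points ranged over -0.48 to 1.16 for alveolar macrophage-like, -0.043 to 0.94 for classical monocyte-like, -0.23 to 1.09 for neutrophil-like and -0.32 to 1.02 for non-classical monocyte-like. Differences between classes ranged over 0.65 to 0.86 for B2m in type 2-like minus aerocyte-like, -0.68 to 0.037 for Il1b in alveolar macrophage-like minus dendritic cell-like, -0.089 to 0.14 for Il1b in classical monocyte-like minus non-classical monocyte-like and -0.14 to 0.46 for Il1b in non-classical monocyte-like minus dendritic cell-like. Single genes ranged over -0.092 to 0.046 for Casp1 in alveolar macrophage-like, -0.18 to 0.21 for Casp1 in capillary-like, -0.29 to 0.35 for Il18 in non-classical monocyte-like, -0.23 to 0.27 for Il1r1 in aerocyte-like, -0.053 to 0.067 for Il1r1 in capillary-like, -0.14 to 0.51 for Il1r2 in dendritic cell-like, -0.076 to 0.054 for Il1rn in alveolar macrophage-like, -0.12 to 0.066 for Il1rn in neutrophil-like, -0.12 to 0.20 for Nlrp3 in classical monocyte-like and -0.27 to 0.079 for Nlrp3 in dendritic cell-like.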

Other observations

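The clock test in this part was chosen after the result was seen, and so were the genes named in it. Across the 12 classes tested, some genes were called in the same direction in several. The inducible chaperone genes Hspa1a and Hspa1b were each lower in HFpEF in 5 classes, of 7 and 6 in which they were measured. Ccnd3, a D-type cyclin gene, was lower in 5 of 12 classes and had a negative fold change in all 12. Zbtb16, a glucocorticoid-induced gene, was lower in 4 of 9 classes, and Nfkbia and Atf3, both induced by stress signals, in 4 of 12 and 4 of 11. Nr1d1 was higher in 4 of the 5 classes that measured it, and the mitochondrially encoded gene mt-Nd3 in 4 of 12. The predicted genes Gm42418 and Gm10076 were lower in 4 of 12 and 3 of 12 classes, and the surfactant gene Sftpc in 3 of 6. Of the MHC class II genes, Cd74 was called lower in 3 of 12 classes and H2-Eb1 in 3 of 11. Both had a negative fold change in every class that measured them, and H2-Aa and H2-Ab1 in 10 and 8 of 11. Whether RNA shared by all cells of a library differed was not tested as such. Sftpc was at 64.3 and 1.10 CPM in control and HFpEF macrophage-like cells. It was at 20.9 and 0 CPM in classical monocyte-like and 62.7 and 0 CPM in dendritic cell-like cells (exact permutation p = 0.0286 each, unadjusted). Its HFpEF mean was the higher one in B cell-like, capillary-like, aerocyte-like and pericyte-like cells (smallest exact permutation p = 0.371). The same mice gave the cells of every class, so that classes are not independent. Endothelial RNA was held by 77.5% of fibroblast-like and 99.3% of pericyte-like cells of HFpEF mice.

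A hypothesis is that the mice of the 2 groups were killed, or sat, at a different phase of the daily clock, because Nr1d1 and Arntl move in opposite directions over the day. In 4 classes that measured both genes, a different clock phase in the mice of the 2 groups would raise Nr1d1 and lower Arntl, and the signs went that way in 4. The log2 fold change of Nr1d1 was 1.51 in capillary-like, 1.19 in fibroblast-like and 1.94 in pericyte-like cells, all called, and 0.74 in type 2-like cells (adjusted p = 0.0954). Arntl had -0.81 (SE 0.155) in capillary-like cells, the 1 class of the 4 with a call, and -0.29 (SE 0.243), -0.05 (SE 0.24) and -0.25 (SE 0.27) in the others, near their errors. With endothelial RNA in those classes, the 4 signs are not 4 separate tests, and the hypothesis rests on capillary-like cells. The times of death were not given in the sources used here, and an effect of the diet and drug on the clock stays open and untested.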
